A study of Homo sapiens with 6 samples.

How the data were processed

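Total RNA of Hep3B cells, an established human hepatocellular carcinoma line, was profiled on 6 Affymetrix HG-U133 Plus 2 arrays. Per the labels' protocols, cells were transduced at a multiplicity of infection of 5 for 48 hours with lentiviral particles that encode an inhibitor of the miR-17 family or a control, both of the kind abbreviated TuD (tough decoy, an RNA with exposed microRNA binding sites). Puromycin selection followed, and after 2 weeks the resistant colonies were pooled into stable lines. The labels give 3 arrays for the miR-17 TuD line and 3 for the NC TuD line. They do not say that the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical, and each group rests on the pooled line made for it. Each sample description also holds a second code, which includes 72HR for all 6 arrays, PLUSDOX for the miR-17 TuD arrays and NODOX for the NC TuD arrays. Its meaning is not given in the sources used here, and it follows the group in 6 of 6 arrays, so it cannot be separated from the decoy.

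The values analysed are the authors' deposited log2 values, 1 per probe set and array. The submitters' processing notes name RMA and GCRMA, with no version and no role for either, and the array software and genome build are not given in the sources used here. The deposited log2 values ran from a shared lowest value of 2.12 to 16.3, with 34.9% to 35.4% of probe sets at the lowest value on each array, a shape that GCRMA gives. Quantiles of the 6 arrays were nearly equal, with medians from 2.75 to 2.78, so the values were kept as deposited. A floor of this kind hides changes of weakly expressed genes, and background correction and normalization between arrays can shrink or stretch small differences. The files hold no detection calls and no scan dates, so neither was used here. The number of arrays limits the precision.

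Of 54675 probe sets, 62 are control probe sets and were left out of the tests. GEO's platform annotation pairs 41091 of the others with 1 gene symbol, 1801 with several and 11721 with none. Symbols were updated through Entrez identifiers against the RefSeq genes of GRCh38.p14, where 41037 probe sets matched. Probe sets with several symbols were not named. No coordinates are printed, because the files name no genome build. Probe sets whose mean over the 6 arrays was at or under the 40th percentile of such means (2.14) were left out, which left 32768 probe sets. For the gene level, each gene was represented by its probe set with the highest mean over all 6 arrays among those with exactly 1 symbol, giving 13949 genes. Probe sets with the suffix s_at or x_at can bind transcripts of more than 1 gene or of related genes.

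The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The estimated prior degrees of freedom were 0.72, so each gene's variance rests mostly on its own 6 values. In 1922 genes the 3 values of a group were identical in every deposited digit, and 1 of these genes passed the threshold. With a tolerance of 0.001 on the log2 scale there were 2051 such genes, 4 of them past the threshold. Before the data were examined, the samples, tests, alternatives, rule for named genes and 31 gene lists were fixed. The lists hold 637 genes, of which 525 were tested. The 28 lists with at least 5 measured genes were tested with camera of limma at its preset correlation of 0.01 between genes, with an estimated correlation, and with fry. Fry tests whether the members of a list move, on balance, 1 way and does not compare them with other genes. List counts are also given adjusted over the list alone.

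The rule for named genes took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, a fixed panel of 16 genes whatever their values, of which 13 were tested and the others are not reported here, and up to 4 members past the threshold with the largest change in each list. Genes named outside this rule are marked where they appear. A planned test of genes with a miR-17 binding site in the 3′ UTR, and the part of the rule that depended on it, were not run, because no 3′ UTR sequences were used here. Differences between 3′ and 5′ control probe sets of GAPDH and ACTB were compared with a 2-sided exact permutation test, for which the smallest p of 3 against 3 arrays is 0.1.

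The pipeline was tested on simulated data made from the real means and each gene's own SD, with 200 of 13949 genes changed in each of 20 simulations. The changed genes were drawn only from genes with a mean level above the median, so recovery of weakly expressed genes was not tested. Among the genes drawn, the pipeline recovered 36.3% of those changed by 0.25, 77.9% of those changed by 0.5 and 97.7% of those changed by 1 on the log2 scale. Of the calls, 7.04% were false, above the nominal 5%. A list planted with a log2 shift of 0.25 was called in 20 of 20 simulations. The simulated noise was independent between genes, while correlations estimated within the real lists reached 0.29. The planted list therefore does not test the list calls under such correlation. Alternatives covered the filter, quantile normalization and median centring, the variance model, array weights, the replicate number as a block, the threshold, the choice of probe set, the list test, and leaving out each array in turn.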

Results

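Transcript levels were measured in Hep3B hepatocellular carcinoma cells carrying a stable decoy RNA against the miR-17 family (miR-17 TuD, 3 arrays) or a control decoy (NC TuD, 3 arrays). All values are log2 expression on Affymetrix arrays, and differences are miR-17 TuD minus NC TuD. Arrays of a group correlated at r of 0.9989 to 0.9993 across probe sets and arrays of different groups at 0.9977 to 0.9984, and no array duplicated another. The first principal component held 59.0% of the variance across genes and separated the groups. On the second, with 15.5%, the miR-17 TuD arrays were spread widely (8.55, 3.23 and -10.37) and the NC TuD arrays little (-0.30, 0.15 and -1.27).

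The comparison addressed which transcripts differ when the miR-17 family, microRNAs that repress their target mRNAs, is inhibited. Of 66 measured genes reported as miR-17 family targets, 23 rose, led by ZNFX1, which encodes a helicase-like zinc finger protein, at 2.37-fold (log2 difference 1.25, SE 0.053), and GPR137B, which encodes a lysosomal membrane protein, at 2.23-fold (1.16, SE 0.096). Of 20 measured genes for proteins that hepatocytes secrete, 19 fell, led by APOA1, the main apolipoprotein of high-density lipoprotein, which was 2.48-fold lower (log2 difference -1.31, SE 0.061), and AFP, the fetal liver protein alpha-fetoprotein, which was 2.40-fold lower (-1.27, SE 0.13). Metallothionein genes and the immediate early gene EGR1 also rose. Outside these groups, the largest changes were a rise of ENPP5 at 3.59-fold and a fall of LGALS14 at 4.46-fold lower.

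In all, 1588 of 13949 genes passed the threshold in limma with Benjamini-Hochberg adjustment, 946 higher and 642 lower in the miR-17 TuD arrays. Most changes were small, with a median absolute log2 difference of 0.27 among the called genes, a 1.21-fold change. A change of at least 1.5-fold was found in 179 of them (116 higher, 63 lower) and of at least 2-fold in 30 (15 higher, 15 lower). Among 4106 genes with a mean level of 7 or less, 69 were called, against 1519 of 9843 above it. At the probe set level, 1910 of 32768 passed (1098 higher, 812 lower). The count of genes fell to 816 without miR-17 TuD replicate 2, and to 387, 375 and 514 without NC TuD replicates 1, 2 and 3. Of the 100 named genes past the threshold, 35 passed it in each of the 6 fits that left out 1 array.

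**Figure D1:**
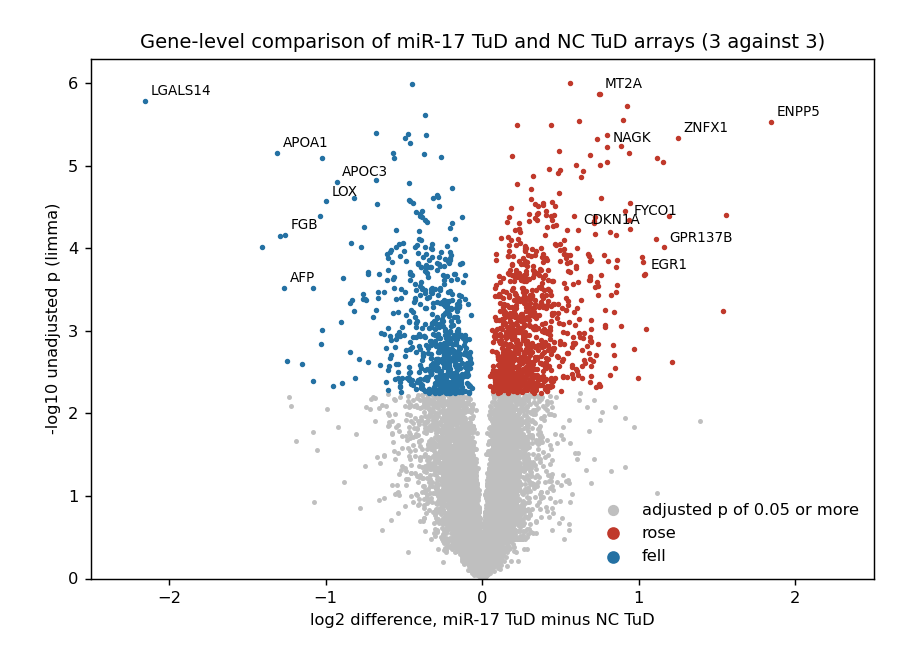
Log2 difference between miR-17 TuD and NC TuD arrays (x axis) against -log10 of the unadjusted limma p (y axis) for 13949 genes. Red points are the 946 genes that rose, blue points the 642 that fell, and grey points did not pass an adjusted p of 0.05.

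On the list of reported miR-17 family targets, 23 members rose and 2 fell, and 33 rose and 8 fell adjusted over the list alone. After ZNFX1 (10.46 ± 0.053 against 9.21 ± 0.084, SD, n = 3, adjusted p = 0.00338 in limma) and GPR137B (10.35 ± 0.15 against 9.20 ± 0.11, adjusted p = 0.009), the largest rises were those of FYCO1, an adaptor for autophagosome transport, at 1.91-fold, and NAGK, an amino sugar kinase, at 1.74-fold. CRIM1 (-0.24) and CNOT6L (-0.14), the members that fell, were chosen for naming after their values were seen. The list median was 0.15, camera gave an adjusted p of 1.39e-05 and fry of 0.000327, and the camera call was lost at adjusted p = 0.116 with an estimated correlation. The correlation estimated for this list was 0.0096, near the preset 0.01. The loss therefore came with that form of the test and not with a larger correlation between members. The list was assembled from general knowledge of the family, and whether any member was first reported from these samples was not examined. The number that rose was 11, 11, 11 and 12 without miR-17 TuD replicate 2 and NC TuD replicates 1, 2 and 3, and none fell without any 1 of the NC TuD arrays. With quantile normalization or the 60th percentile filter, 4 fell. The number that rose was 15 of 51 measured members with probe sets of suffix s_at and x_at left out and 14 of 71 with no filter on low values, and none fell in either.

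Within the fixed panel, CDKN1A, which encodes the cell cycle inhibitor p21, rose 1.53-fold (13.16 ± 0.071 against 12.55 ± 0.046, adjusted p = 0.00736 in limma). TGFBR2, the type II TGF-beta receptor, rose 1.46-fold (11.97 ± 0.049 against 11.43 ± 0.056, adjusted p = 0.00736), and E2F1, a cell cycle transcription factor, rose 1.26-fold (7.70 ± 0.03 against 7.36 ± 0.089, adjusted p = 0.0255). The E2F1 call ended in 5 of the 6 fits that left out 1 array, all but the fit without NC TuD replicate 3, with adjusted p up to 0.101, and with no filter on low values (adjusted p = 0.0532). MCM7, the host gene of a paralogous microRNA cluster, differed by 0.10 (adjusted p = 0.0983), ZBTB4 by 0.22 (adjusted p = 0.134) and BCL2L11 by 0.07 (adjusted p = 0.635), all short of the threshold. TP53INP1 (-0.30, adjusted p = 0.0956), TXNIP (-0.17, adjusted p = 0.129) and BMPR2 (-0.12, adjusted p = 0.275) did not pass either. ZBTB4 passed without miR-17 TuD replicate 1 (adjusted p = 0.0264), TP53INP1 passed with the filter at the 60th percentile (adjusted p = 0.0432), and the BMPR2 difference was 0.0018 when the probe sets of the gene were averaged.

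**Figure D2:**
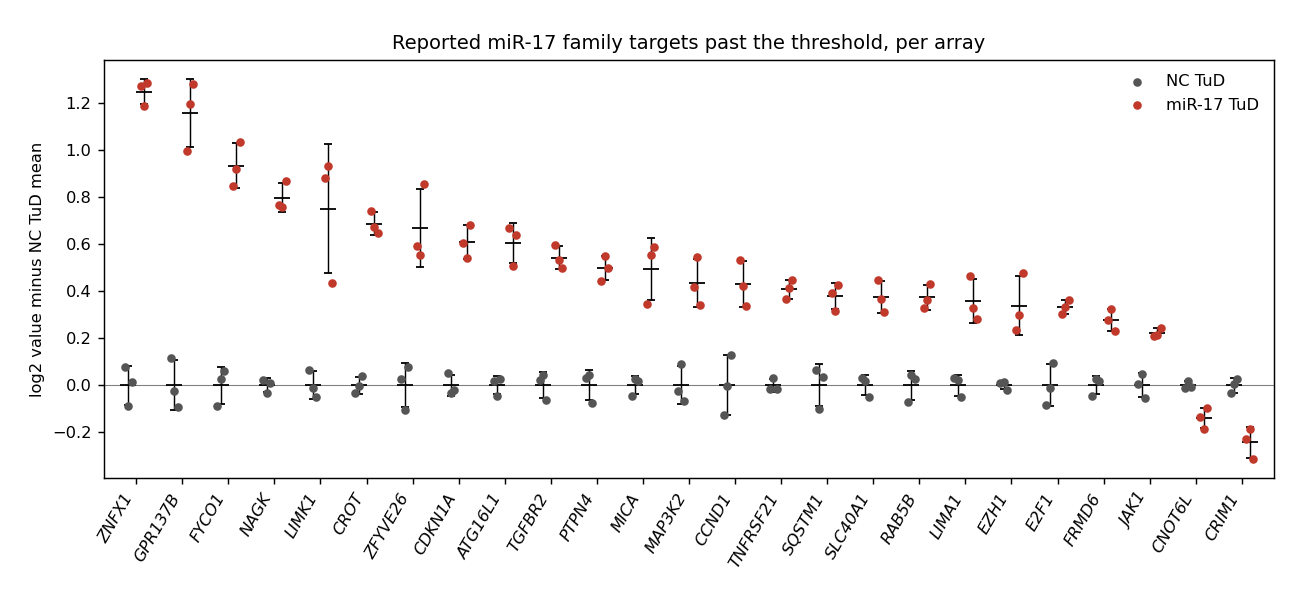
Log2 values of each array minus the NC TuD mean (y axis) for the reported miR-17 family targets past the threshold (x axis), with NC TuD arrays in grey and miR-17 TuD arrays in red. Bars show mean and SD of 3 arrays, and the miR-17 TuD arrays lie above the NC TuD arrays for 23 genes and below for CRIM1 and CNOT6L.

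Hepatocyte secreted protein genes fell in 19 of 20 measured members, and none rose. Adjusted over the list alone, 19 fell and 1 rose, SERPINA1, at 0.13 with an adjusted p of 0.0912 over all genes in limma, a gene chosen for naming after its value was seen. APOA1 stood at 9.94 ± 0.1 against 11.25 ± 0.056 (SD, n = 3, adjusted p = 0.00338), AFP at 7.82 ± 0.24 against 9.08 ± 0.063 (adjusted p = 0.0122), FGB, the fibrinogen beta chain, at 9.62 ± 0.17 against 10.87 ± 0.062 (adjusted p = 0.00787) and APOC3, an apolipoprotein of triglyceride-rich lipoproteins, at 10.05 ± 0.079 against 10.98 ± 0.055 (adjusted p = 0.00482). ALB, which encodes serum albumin, stood near the upper end of the scale at 15.99 ± 0.033 against 16.20 ± 0.036 (-0.21, adjusted p = 0.0169), and its call was lost with quantile normalization (-0.11, adjusted p = 0.219). The list median was -0.47, with an adjusted p of 7.47e-16 in camera and 9.68e-05 in fry, and adjusted p = 0.0538 with an estimated correlation. The number that fell was 9, 8 and 9 without NC TuD replicates 1, 2 and 3, and the AFP call ended without any 1 of the NC TuD arrays (adjusted p up to 0.0612), and the ALB call without any of these or miR-17 TuD replicate 1 (up to 0.0726). With probe sets of suffix s_at and x_at left out, 8 of 11 measured members fell, ALB at -0.44, and SERPINA1 rose at 0.91 (adjusted p = 0.0333), as it did with averaged probe sets (0.38, adjusted p = 0.0353).

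**Figure D3:**
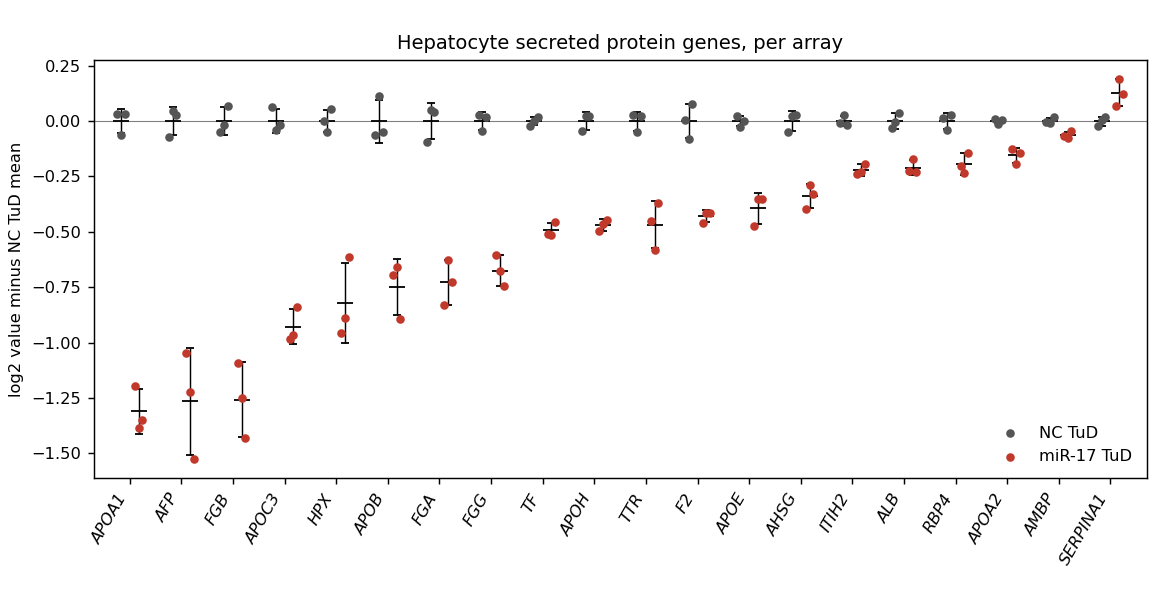
Log2 values of each array minus the NC TuD mean (y axis) for 20 hepatocyte secreted protein genes (x axis), with NC TuD arrays in grey and miR-17 TuD arrays in red. Bars show mean and SD of 3 arrays, and mean differences run from -1.31 for APOA1 to 0.13 for SERPINA1.

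Hepatocyte transcription factor and metabolic enzyme genes fell in 4 of 14 measured members, ONECUT1 (-0.46), PROX1 (-0.39), NR5A2 (-0.28) and CEBPA (-0.22), all of them transcription factors, and none rose. Adjusted over the list alone the count was also 4. Camera gave an adjusted p of 0.0476, with adjusted p = 0.368 with an estimated correlation, and the call of the list ended without miR-17 TuD replicates 1 or 3 or NC TuD replicate 3 and with array weights or no filter. The number that fell was 1, 2 and 2 without miR-17 TuD replicates 1, 2 and 3 and 1, 0 and 1 without NC TuD replicates 1, 2 and 3. It was 2 of 18 with no filter and 2 of 11 without s_at and x_at probe sets, and PCK2, named after its value was seen, rose by 0.07 without miR-17 TuD replicate 1. Among the 6 fits that left out 1 array, the PROX1 call ended in all, the NR5A2 and CEBPA calls in 5 and the ONECUT1 call without NC TuD replicate 2. The PROX1 and CEBPA calls also ended with no filter and without s_at and x_at probe sets, and the PROX1 call with array weights. NR5A2 stood at -0.45 with averaged probe sets.

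Among the 10 largest rises, ENPP5, a member of the ectonucleotide pyrophosphatase family, stood at 10.06 ± 0.11 against 8.22 ± 0.079 (SD, n = 3, adjusted p = 0.00338 in limma), CHODL, a membrane protein of the C-type lectin family, at 8.85 ± 0.18 against 7.30 ± 0.077 (adjusted p = 0.00654) and COMP, a cartilage matrix protein, at 7.47 ± 0.32 against 5.93 ± 0.14 (adjusted p = 0.0158). The others were ZNFX1, ADAMTSL2 (1.21), BHMT (1.19), GPR137B, CST6 (1.16), SPINK1 (1.12) and DOK7 (1.11). Among the 10 largest falls, LGALS14, a galectin, stood at 7.66 ± 0.092 against 9.82 ± 0.1 (adjusted p = 0.00338), NSUN7 fell by 1.40, the amino acid transporter SLC6A14 fell by 1.29 and the chromatin organizer SATB1 fell by 1.25 on the log2 scale. APOA1, AFP and FGB were also among them, with GATA3 (-1.15), SCUBE3 (-1.08) and ALDH8A1 (-1.08). GATA3 stood at 2.76 ± 0.036 in the miR-17 TuD arrays, close to the lowest value on the arrays, and ADAMTSL2 at 4.15 in all 3 NC TuD arrays, equal within 0.001, as at a floor, so the sizes and ranks of these 2 changes are not firm. The SATB1 call ended in all 6 fits that left out 1 array, the GATA3 and SCUBE3 calls in 5, the COMP and ADAMTSL2 calls without miR-17 TuD replicate 2 or any 1 NC TuD array, and the ALDH8A1 call without any 1 NC TuD array (adjusted p from 0.0521 to 0.129 over these fits). With no filter the ADAMTSL2, SATB1, GATA3 and SCUBE3 calls ended, with array weights the GATA3 and SCUBE3 calls, and without s_at and x_at probe sets the SCUBE3 call. Averaged probe sets gave 1.94 for CST6 and -0.38 for SCUBE3.

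Metallothionein and NRF2 target genes rose in 9 of 15 measured members, and none fell. Adjusted over the list alone, 10 rose and 1 fell. Among 8 genes with the symbol root MT, a grouping chosen after the results were seen, 7 rose, with a median of 0.74. The list count mixes metallothioneins with NRF2 targets and is not read as an NRF2 response. Metal-binding metallothioneins MT1F (1.85-fold), MT1G (1.81-fold), MT1X (1.74-fold) and MT2A (1.68-fold, 13.92 ± 0.012 against 13.17 ± 0.043, adjusted p = 0.00338 in limma) rose most. The list median was 0.46, with an adjusted p of 1.2e-05 in camera and adjusted p = 0.368 with an estimated correlation. These 4 genes were measured by probe sets of suffix x_at, which paralogs can share, and with such sets left out 1 of 6 measured members rose. The count was 5 without any 1 of the NC TuD arrays, and the MT1F call ended without miR-17 TuD replicates 1 or 3 or NC TuD replicates 2 or 3, the MT1G call without NC TuD replicate 1.

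Immediate early genes rose in 5 of 15 measured members, 7 adjusted over the list alone, and none fell. EGR1 rose 2.06-fold (11.22 ± 0.14 against 10.18 ± 0.13, adjusted p = 0.0105 in limma), KLF2 1.65-fold, IER2 1.16-fold and JUNB 1.11-fold, all nuclear regulators induced early by growth signals or stress. Camera gave an adjusted p of 1.73e-05, with adjusted p = 0.368 with an estimated correlation. KLF2 differed by 0.10 (adjusted p = 0.545) on a probe set without the s_at suffix, and by 0.41 with averaged probe sets. The count was 2 without any 1 NC TuD array, 3 without miR-17 TuD replicate 2 and 2 of 10 without s_at and x_at probe sets. The IER2 call ended without any 1 NC TuD array, and the JUNB call with no filter and in all fits that left out 1 array but that without miR-17 TuD replicate 1.

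Hypoxia and glycolysis genes rose in 2 and fell in 6 of 23 measured members, the same counts adjusted over the list alone. PFKP, a phosphofructokinase, rose 1.92-fold (8.76 ± 0.12 against 7.82 ± 0.051, adjusted p = 0.00736 in limma), and EGLN3, an oxygen-sensing prolyl hydroxylase, rose 1.38-fold. The glucose transporter SLC2A3 (-0.58) and the glycolysis regulator PFKFB4 (-0.45) fell. The list median was -0.099, with an adjusted p of 0.00412 in camera and adjusted p = 0.441 with an estimated correlation. The number that fell was 2 without NC TuD replicate 1, 2 without NC TuD replicate 2 and 3 of 13 without s_at and x_at probe sets. The PFKFB4 call ended without miR-17 TuD replicate 1 or any 1 NC TuD array and with no filter, and the gene stood at -0.23 with averaged probe sets.

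Cholesterol synthesis genes fell in 4 of 18 measured members and rose in 1, or 7 and 1 adjusted over the list alone. HMGCS1 (-0.41), SC5D (-0.33) and SQLE (-0.28), enzymes of the pathway, fell, and MVK, mevalonate kinase, rose (0.31). Camera gave an adjusted p of 0.00736, with adjusted p = 0.441 with an estimated correlation. SC5D was 0.015 on a probe set without the s_at suffix and -0.16 with averaged probe sets, the MVK call ended in all 6 fits that left out 1 array and with no filter, array weights or s_at and x_at probe sets left out, and 2 genes fell without miR-17 TuD replicates 1 or 2 or NC TuD replicates 2 or 3, fits in which the SQLE call ended. Without s_at and x_at probe sets 2 of 13 fell and none rose.

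Genes of the NF-kB and acute phase list fell in 3 and rose in 1 of 16 measured members, or 5 and 1 adjusted over the list alone. The NF-kB inhibitors TNFAIP3 (-0.52) and NFKBIA (-0.21) and the chemokine CCL20 (-0.31) fell, and the chemokine CXCL8 rose (0.18). Camera gave an adjusted p of 0.016, with adjusted p = 0.368 with an estimated correlation. The calls of the 4 genes ended in 1 to 5 of the 6 fits that left out 1 array, each of them without NC TuD replicate 2. The TNFAIP3 (adjusted p = 0.0959) and CXCL8 (adjusted p = 0.0597) calls also ended with no filter, and the TNFAIP3 call with the robust variance model (adjusted p = 0.0539). The number that fell was 4, 1 and 2 without miR-17 TuD replicates 1, 2 and 3 and 1, 0 and 1 without NC TuD replicates 1, 2 and 3. NFKBIA differed by -0.025 (adjusted p = 0.491) on a probe set without the s_at suffix and by -0.12 with averaged probe sets, and 1 of 9 measured members fell without s_at and x_at probe sets. With the 60th percentile filter 5 fell, and CXCL1 (-0.21) and CXCL2 (-0.20), the members added, were named after their values were seen.

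Camera called 4 further lists upward, with small changes. MYC-regulated and ribosome biogenesis genes rose in 4 of 20 (14 adjusted over the list alone), among them ODC1 (0.34), the first enzyme of polyamine synthesis, and NME1 (0.27), with a median of 0.18, a camera adjusted p of 3.7e-05 and adjusted p = 0.394 with an estimated correlation. Cytosolic ribosomal protein genes rose in 4 of 19 (8 adjusted over the list alone), RPL14 (0.16), RPL8 (0.12), RPS9 (0.11) and RPL19 (0.09), with a camera adjusted p of 0.000628 and adjusted p = 0.441 with an estimated correlation. Of 24 G1/S genes 5 rose (7 rose and 3 fell adjusted over the list alone), including the cyclins CCNE1 (0.32) and CCNE2 (0.31) and the replication origin gene ORC1 (0.38), with a camera adjusted p of 0.0205 and adjusted p = 0.485 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose in 3 of 23 (5 adjusted over the list alone), NDUFA9 (0.23), UQCRC1 (0.15) and NDUFS1 (0.15), with a camera adjusted p of 0.0493 and adjusted p = 0.553 with an estimated correlation. The oxidative phosphorylation call also ended in fry (adjusted p = 0.13), under both other scalings, with array weights, averaged probe sets or the 60th percentile filter, and without miR-17 TuD replicate 1 or NC TuD replicate 2. The G1/S call ended with quantile normalization (adjusted p = 0.118), the 60th percentile filter, and without miR-17 TuD replicate 3. NDUFS1 turned to -0.0061 with probe sets averaged, and RPL14 differed by 0.030 (adjusted p = 0.88) without s_at and x_at probe sets. Its call also ended with quantile normalization or averaged probe sets, that of RPS9 with the 60th percentile filter, either other scaling or array weights, and that of RPL19 with the 60th percentile filter. The ORC1 and CCNE1 calls ended without s_at and x_at probe sets and the ORC1 call with array weights. Among the 6 fits that left out 1 array, the calls of ORC1, RPL14, RPS9 and NDUFS1 ended in all, those of CCNE1 and UQCRC1 in 5, that of RPL19 in 4 that of NME1 without NC TuD replicates 1 or 2 and those of RPL8 and NDUFA9 without NC TuD replicate 1. The calls of ORC1, CCNE1, RPL14, RPS9, UQCRC1 and NDUFS1 also ended with no filter.

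In each of these 4 lists, fewer genes rose in every fit that left out 1 array. Ribosomal protein genes numbered 2, 1 and 2 without miR-17 TuD replicates 1, 2 and 3 and 0, 1 and 1 without NC TuD replicates 1, 2 and 3. Without the same NC TuD replicates 1, 2 and 3, the MYC and ribosome biogenesis list had 1, 1 and 2, the G1/S list 1, 1 and 1 and the oxidative phosphorylation list 0, 1 and 1. The G1/S count was 3 and 1 without miR-17 TuD replicates 1 and 2. The MYC count was 8 with the 60th percentile filter, 7 with median centring and 2 with no filter, and the ribosomal count was 2 with that filter, with no filter and with quantile normalization.

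The list of G2/M and mitosis genes was not called by camera (adjusted p = 0.205), and its median was -0.030 with 19 of 25 members lower. The list was called downward with quantile normalization (adjusted p = 0.0449), averaged probe sets (adjusted p = 0.0371) and without miR-17 TuD replicate 1 (adjusted p = 0.0273), and 7 of the 10 splits of the arrays, the real one included, gave a camera p as small. Only KIF23 (0.35) and UBE2C (0.07) passed in limma, both upward, and each call ended in 5 of the 6 fits that left out 1 array and with no filter. KIF23 differed by 0.13 (adjusted p = 0.262) with averaged probe sets and by -0.095 (adjusted p = 0.597) without s_at and x_at probe sets, and the UBE2C call ended with the 60th percentile filter or either other scaling.

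**Figure D4:**
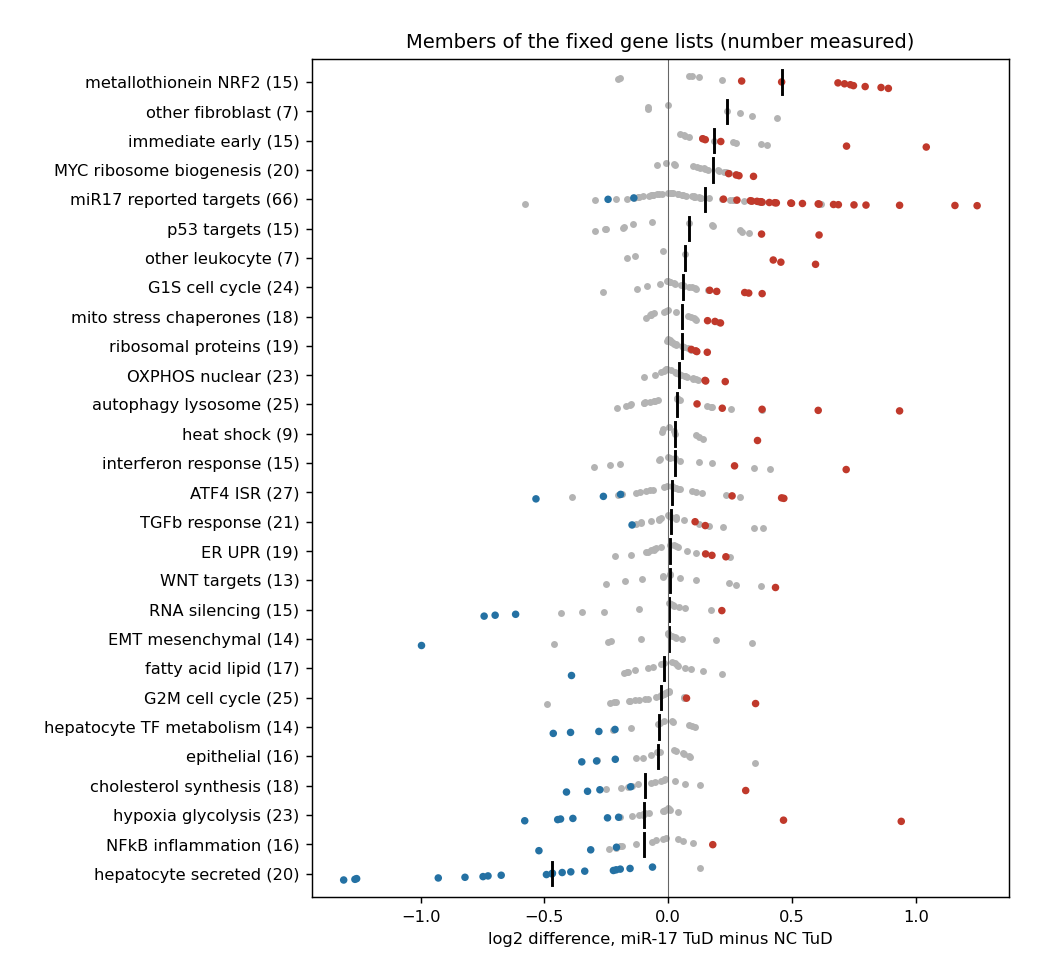
Log2 difference, miR-17 TuD minus NC TuD (x axis), of each measured member of the 28 tested gene lists (y axis, number measured in brackets). Red and blue points rose and fell past the threshold, grey points did not pass, black bars are list medians, and the lowest median is the -0.47 of the hepatocyte secreted list.

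Camera called 12 of the 28 lists, 7 upward and 5 downward, and none with an estimated correlation, while fry called 18. The estimates for the target list (0.0096) and the hepatocyte factor list (0.0105) were near the preset 0.01. A call lost in this form of the test is thus not by itself a sign of correlation between members. Lists without a camera call still held changed genes. Of all 13949 genes, 11.4% were called, with 16.6% at mean levels from 9 to 11 and 18.3% from 11 to 13. The counts of the autophagy, p53, interferon, mesenchymal and epithelial lists are close to or under these shares. So is that of the oxidative phosphorylation list above. These counts are therefore not read as results about the lists. Of 15 RNA silencing genes, the decapping enzyme DCP2 (-0.74), the Argonaute AGO4 (-0.70) and the Argonaute partner TNRC6B (-0.62) fell and the microRNA precursor exporter XPO5 rose (0.22), and each of these calls ended without NC TuD replicates 1 or 2. The DCP2 call also ended without NC TuD replicate 3, the AGO4 and XPO5 calls without miR-17 TuD replicates 1 or 2, and the TNRC6B call without miR-17 TuD replicate 3 or NC TuD replicate 3 and with no filter. With averaged probe sets DCP2 stood at -0.39, AGO4 at -0.28 and TNRC6B at -0.32, the last short of the threshold (adjusted p = 0.0636). Autophagy and lysosome genes rose in 5 of 25, including FYCO1, ATG16L1 (0.61), SQSTM1 (0.38) and ATG7 (0.22), and the first 3 of these are also on the target list. The ATG16L1 (0.17, adjusted p = 0.391), SQSTM1 (0.22, adjusted p = 0.139) and ATG7 (0.24, adjusted p = 0.056) calls ended with averaged probe sets. Those of SQSTM1 (0.11, adjusted p = 0.382) and ATG7 (0.11, adjusted p = 0.545) also ended without s_at and x_at probe sets, where none of 15 measured members rose. The autophagy count was 3 with averaged probe sets, where 2 members fell, 2 without any 1 NC TuD array or miR-17 TuD replicate 2, and 3 without miR-17 TuD replicates 1 or 3 or with no filter.

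The p53 target list held CDKN1A, which is also on the miR-17 target list, and the death receptor TNFRSF10B (0.38) as its rises among 15. Hep3B cells are known to lack p53, so changes on this list are not read as a p53 response. The interferon list held IRF9 (0.72) and ISG15 (0.27) as its rises among 15. The SQSTM1 and ISG15 calls ended in all 6 fits that left out 1 array and with no filter, the IRF9 call without any 1 NC TuD array, the ATG7 call without these or miR-17 TuD replicate 2, and the TNFRSF10B call without NC TuD replicates 1 or 2. Of the p53 list, 4 rose without NC TuD replicate 3, with AEN (0.40) and PLK3 (0.24) added. With quantile normalization, median centring or the 60th percentile filter 4 rose as well, with AEN and DDB2 (0.30 to 0.31) added, and BAX fell (-0.24 to -0.26), as TP53INP1 also did with that filter. With averaged probe sets BAX and MDM2 (-0.10) fell, without miR-17 TuD replicate 1 BAX fell and without replicate 2 MDM2 fell (-0.26). AEN, PLK3, DDB2, BAX and MDM2 were named after their values were seen. In the interferon list 1 gene rose without any 1 miR-17 TuD array or with no filter and none without any 1 NC TuD array. LOX, a collagen cross-linking enzyme, fell by 1.00 on the log2 scale, the 1 gene of 14 on the mesenchymal list past the threshold with all 6 arrays. ZEB1 fell besides LOX without miR-17 TuD replicate 3 (-0.30, adjusted p = 0.041) and COL1A1 rose without replicate 1 (0.51), both named after their values were seen, and none of the 9 members measured without s_at and x_at probe sets, LOX not among them, passed. The junction genes OCLN (-0.35), CDH1 (-0.29) and TJP1 (-0.21) fell among 16 epithelial genes, and the OCLN and TJP1 calls ended in all 6 fits that left out 1 array and the CDH1 call in 5. With no filter none of the 3 calls held, and the OCLN call ended with array weights. The number of epithelial genes that fell was 5 with quantile normalization, which added DSP (-0.12) and MARVELD2 (-0.15), and KRT18 rose without miR-17 TuD replicate 2 (0.10), genes named after their values were seen. In the amino acid stress list of 27, 3 genes rose, among them ATF5 (0.47) and VLDLR (0.46), and 3 fell, among them STC2 (-0.53) and CHAC1 (-0.26). The ATF5, VLDLR and CHAC1 calls each ended in 5 of the 6 fits that left out 1 array and with no filter, the ATF5 call ended with array weights, and ATF5 stood at 0.12 (adjusted p = 0.0588) with averaged probe sets. Without NC TuD replicates 1, 2 and 3, 0, 0 and 1 genes of this list rose and 1 fell in each. Without miR-17 TuD replicate 1, 4 rose and 1 fell, without replicate 2, 1 rose and 1 fell, and without replicate 3, 1 rose and 5 fell, with DDIT4 (-0.47) and PSAT1 (-0.08) added, genes named after their values were seen. With no filter 1 rose and 1 fell, and without s_at and x_at probe sets none of 17 rose and 2 fell.

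Markers of other cell types were measured as a check of the samples. Of 7 leukocyte markers, LYZ (0.59), LAPTM5 (0.45) and CORO1A (0.42) rose, with adjusted p of 0.0193, 0.0411 and 0.0448 in limma, and these calls ended without miR-17 TuD replicate 2 or any 1 NC TuD array, that of LAPTM5 also without miR-17 TuD replicate 3 and that of CORO1A in all 6 such fits, with array weights and without s_at and x_at probe sets. LYZ differed by 0.071 (adjusted p = 0.738) without s_at and x_at probe sets and by 0.33 (adjusted p = 0.0706) with averaged probe sets, which gave LAPTM5 0.28 (adjusted p = 0.0771). With no filter 1 of 11 leukocyte markers rose. The other 4, CD3D (-0.17), CD14 (-0.14), CD79A (0.07) and FCER1G (-0.02), named after their values were seen, did not pass and had group means from 2.39 to 3.85. No fibroblast marker of 7, endothelial marker of 3 or erythroid or neural marker of 4 passed the threshold with all 6 arrays in the comparison as designed. Some of these markers were well expressed in the NC TuD arrays, such as COL1A1 (12.45) and SNAP25 (11.72), and others were low, such as THY1 (3.47) and PECAM1 (2.43). The well expressed ones cannot show whether other cells were present. SNAP25, THY1 and PECAM1 were named after their values were seen. The fibroblast markers had a median of 0.24 (camera adjusted p = 0.361), against 0.11 at most in the other splits of the arrays. Without miR-17 TuD replicate 1, COL1A2 (0.61), COL1A1 (0.51) and PDGFRA (0.35) rose, PDGFRA also did with array weights, the 60th percentile filter or either other scaling, and MAP2, a neural marker, did with averaged probe sets (0.20, adjusted p = 0.044). COL1A2, COL1A1, PDGFRA and MAP2 were also named after their values were seen. Of the RNA quality control probe sets, the 3′ minus 5′ difference of GAPDH was -0.249 ± 0.0098 against -0.253 ± 0.0027 (SD, n = 3, exact permutation p = 0.8). That of ACTB was 0.682 ± 0.0023 against 0.701 ± 0.01 (exact permutation p = 0.1, the smallest possible), a difference of -0.019 with no overlap between the groups, in the same arrays in which the gene groups above differed.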

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

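All alternatives were planned before the data were examined, the test of genes with a miR-17 site was not run, and the cause of the changes below was not tested except where fewer arrays or another number of tested genes is the setting itself. The count of 1588 genes stayed within 1.5 times under quantile normalization, median centring, the other variance models, array weights, averaged probe sets and the 60th percentile filter (1475 to 2104). It was 789 with no filter, 927 without s_at and x_at probe sets, 179 at 1.5-fold or more, 243 at an adjusted p under 0.01, and from 375 to 1259 when 1 array was left out. The 1910 probe sets became 554 with no filter, 3271 with the 60th percentile filter, 263 at 1.5-fold or more, and from 148 to 1157 when 1 array was left out. With the replicate number as a block, 822 genes and 0 probe sets were called in limma, and 628 of the 822 genes were among the 1588. Deviations of arrays with the same number correlated at 0.03, 0.13 and 0.10, and each array correlated best with its own number. The planned main fit did not pair the arrays, and a batch shared by arrays of the same number stays possible. With the block, GPR137B (adjusted p = 0.0552 in limma) and AFP (adjusted p = 0.058) were among the named genes that lost their calls. The block ended the calls of the hepatocyte factor and oxidative phosphorylation lists and of no other list. The 12 lists ranged from 10 to 18 except with an estimated correlation, where 0 were called (smallest adjusted p = 0.0538). Averaging the probe sets of a gene reversed BMPR2 (0.0018) and NDUFS1 (-0.0061). Leaving out s_at and x_at probe sets reversed SC5D (0.015), KIF23 (-0.095), MRPS5 (-0.011), RRP12 (-0.032) and NDUFS1 (-0.00084). The GAPDH difference of 0.0038 reversed to -0.0016 with the middle probe set, and ran from -0.0016 (without miR-17 TuD replicate 2) to 0.0079 when 1 array was left out. The ACTB difference was -0.031 with the middle probe set, 0.613 ± 0.014 against 0.645 ± 0.016 (SD, n = 3, exact permutation p = 0.1), again without overlap. No named gene changed sign under the other settings. Of the 100 named calls, 47 ended with the block, 37 with no filter, 22 of the 71 still measured without s_at and x_at probe sets, 15 with averaged probe sets, 65 at an adjusted p under 0.01, 62 at 1.5-fold or more, and 10 or fewer with each other filter, scaling, variance model or array weights on all 6 arrays. Signal near the shared lowest value limits what weakly expressed genes can show.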

Other observations

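Grouping genes by the root of their symbols, a step chosen after the results were seen, gave 234 families of at least 8 genes, of which camera in limma called 9, 8 upward and 1 downward. Mitochondrial ribosomal protein genes were higher in the miR-17 TuD arrays, with 10 of 48 MRPL genes rising and 1 falling (median 0.085) and 6 of 27 MRPS genes rising (median 0.11). RNA polymerase subunit genes (POLR) rose in 10 of 32 and fell in 1, with a median of 0.081. Zinc finger genes (ZNF) went the other way, with 27 of 421 falling and 7 rising and a median of -0.071. The direction of these medians was the same under quantile normalization and median centring. None of the 9 calls held with an estimated correlation (adjusted p = 0.938 each), and other splits of the arrays gave from 0 to 11 called families.

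Further tests below weigh explanations for 3 patterns. The random lists matched on level were planned before their results were seen, and every other test here was chosen after the result was seen.

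The fall of hepatocyte secreted protein genes could come from a bias of abundant probe sets. Against that, its median of -0.47 lay at percentile 0 of 10000 random lists matched on level, whose medians ran from -0.098 to 0.12. Cells that lack these transcripts would lower all members by about 1 amount, but the log2 differences of the 12 members with an NC TuD level under 14 had an SD of 0.365 against a median standard error of 0.061, from -1.31 for APOA1 to -0.22 for ITIH2, a gene named after its value was seen. A chi-square test of a common fall, computed first, gave p = 9.51e-120, and the SD comparison replaced it after that result was seen. That p treats the standard errors as exact and the genes as independent, so it is far too small and carries no weight here. The SD comparison uses the same members and standard errors, so its outcome was settled once that p was known. It shows unequal falls, which background correction can also stretch or shrink. At most it speaks against dilution as the only source of the fall. An effect of the decoy on these genes is a hypothesis that stays open. So do dilution as a part of the fall, differences between the pooled lines, 1 per group, and an effect of the condition named by the second sample code.

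The rise of reported miR-17 family targets could also come from the level of their probe sets, but its median of 0.15 lay at percentile 100 of 10000 matched random lists, whose medians ran from -0.061 to 0.083. Whether it follows the inhibitor or the condition named by the second sample code cannot be told apart, since the code follows the group in 6 of 6 arrays. Loss of repression by the inhibited microRNAs is the biological hypothesis the design names, and it was not tested on binding sites.

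For the mitochondrial ribosomal protein families, variation between arrays that does not follow the groups may account for the shift, because another split of the 6 arrays gave the MRPL family a camera p of 4.83e-08, against 7.89e-08 for the real split. For MRPS another split gave 1.06e-06, against 5.54e-05. No other split reached the camera p of the POLR (0.00779 at best, against 6.86e-05) or ZNF family (0.000164 at best, against 1.07e-06). A difference in RNA integrity stays open, since 1 of 2 control genes, ACTB, had separated 3′ minus 5′ differences. The condition named by the second sample code cannot be told apart from the decoy here either, since the code follows the group in 6 of 6 arrays. Copy number differences of long chromosome regions between the lines, the explanation tested before the test over splits was added, stay open too. In GRCh38.p14 gene order, the most extreme median over 31 neighbouring genes was 0.157 from the overall median. That was above the 95th percentile of 200 shuffled orders (0.143) and exceeded or matched in 4 of them. It met the written prediction, which concerned any region and not the MRPL genes. The window lay lower in the miR-17 TuD arrays, while the MRPL median was higher, and held 0 of the 48 MRPL genes, which lie on 20 chromosomes. The test therefore cannot decide whether copy number bears on the MRPL rise.

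Among all genes with a level above 7, log2 differences of adjacent genes correlated at a Spearman rho of 0.108, against -0.023 to 0.0285 in the 200 shuffled orders. This correlation is across genes, which are not independent replicates.

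With 10 splits of the 6 arrays, the share of splits with a result as large cannot go under 0.05. The real split gave 1588 genes and 1910 probe sets and the highest other split 0 of each, at 170 to 473 genes of unadjusted p under 0.05 in limma against 3880. Every other split mixes arrays of both groups, so a difference between the groups widens its spread and lowers its counts. The other splits, here and for the lists, are therefore no measure of what chance alone would give. For lists, the real split gave 12 and the highest other 11, and only 1 split of the 10, the real one, reached each of the 3 counts. The camera p of the MYC and ribosome biogenesis, ribosomal protein, cholesterol, G1/S and oxidative phosphorylation lists was as small or smaller in at least 1 other split, and that of the target, secreted, metallothionein, immediate early, hypoxia, hepatocyte factor and NF-kB lists was not. The gap was small for NF-kB (camera p 0.00514 against 0.00539 in another split) and hepatocyte factors (0.0187 against 0.0427). For the secreted list it was large (2.67e-17 against 0.000143). For the hepatocyte factor list, however, 5 of the 10 splits, the real one included, gave an absolute median as large (0.038, against up to 0.046 in another split).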
